A study of Rattus norvegicus with 16 samples.

How the data were processed

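RNA was measured in microglia sorted from brains of 16 male Wistar rat samples, 4 per group, after X-ray or sham irradiation (14 Gy) and an injection of PBS or LPS 6 weeks later. Per the labels, cells were dissociated mechanically in the cold, sorted as DAPI-negative cells with high CD11b and intermediate CD45, and sequenced on a NovaSeq with a low-input library kit. The deposited values are raw read counts per Ensembl gene, and the submitters' processing notes name FastQC 0.11.9, fastp 0.23.2, HTSeq 2.0.2 and the rat build mRatBN7.2. Aligner, annotation release and strand of counting are not given in the sources used here, so reads of close paralogs (ribosomal protein pseudogenes and the RT1, Ly49 and granzyme B families) may be split between copies. Count files held 30560 gene IDs, of which 6518 had no symbol (from 1.85% to 2.28% of the counts of a library), and 246 symbols stood on several IDs. A second table with counts summed over 21842 symbols was compared with the files of single samples, and 0 of 349472 cells differed. A RefSeq table was used for synonyms of gene symbols only.

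Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit with 1 coefficient per group), and 13608 genes were tested. The common biological coefficient of variation was 0.289 and the median prior degrees of freedom 5.71. Adjusted p values are Benjamini-Hochberg values, called under 0.05, and the SE is the fold change over the root of the F statistic. Log2 CPM used a prior count of 2. Comparisons were LPS against PBS in sham and in irradiated rats, irradiated against sham with PBS and with LPS, and the difference between the LPS responses (the interaction). Groups and alternatives were chosen before the data were examined, except the 3 alternatives that the closing section names as added later. Replicate numbers of the titles were treated as numbers and not as pairs.

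Gene lists (40 lists, 1292 genes written from general knowledge, 1119 tested) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated, and with fry, adjusted over the 40 lists of a comparison. Counts of members were also adjusted over the list alone. Members at 0 in a whole group occurred in 12 of 160 list results, and setting them to a floor of 3 counts changed no list median (largest change 0).

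Genes were named by a fixed rule. In each pairwise comparison the rule took the 8 largest positive and 8 largest negative fold changes among called genes with a mean log2 CPM of at least 3, groups that did not overlap and a gene symbol. For the interaction it took 10 in each direction without the overlap condition. Up to 4 members with the smallest p of each described list were added. A panel of 10 genes was always given: P2ry12 (ENSRNOG00000013902), Tmem119 (ENSRNOG00000000700), Cx3cr1 (ENSRNOG00000018509), Sall1 (ENSRNOG00000013907), Apoe (ENSRNOG00000018454), Clec7a (ENSRNOG00000054251), Il1b (ENSRNOG00000004649), Tnf (ENSRNOG00000070745), Ccl2 (ENSRNOG00000007159) and Cdkn1a (ENSRNOG00000000521).

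Alternatives were DESeq2 1.42.0, limma voom with sample weights, other scaling and filters, a fit without robust moderation, a replicate block, only the groups compared, a test against a fold change of 1.5, and leaving out each library. The method was tested on simulated data with known changes. Of genes changed 1.5-fold, 2-fold and 4-fold, 23.9%, 55.2% and 72.7% were called for LPS in sham rats and 2.99%, 35.8% and 59.1% for the interaction, so most small differences in response could not be called. Only 67, 67 and 66 genes were changed at these folds, whereas 4031 real genes were called for LPS in sham rats. Adjustment is stricter with so few changed genes, and genes removed by the filter counted as not called. The shares are thus not the sensitivity of the real pairwise tests. False calls numbered 4 of 105 calls for LPS in sham rats and 6 of 117 for LPS in irradiated rats. They numbered 10 of 112 for irradiation with PBS, 10 of 111 for irradiation with LPS and 4 of 69 for the interaction. The false share thus exceeded the adjusted p threshold for calling in every comparison except LPS in sham rats. All comparisons were simulated from the same means and dispersions, with a single run each. Differences in the false share between comparisons therefore say nothing about irradiation. Of 20 simulated lists shifted by 0.5 on the log2 scale 20 were called, and of 20 lists without a shift 1 was called. Simulated genes varied independently of each other, so these lists do not measure how often a list of correlated genes is called falsely.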

Results

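Gene expression was measured by bulk RNA sequencing of microglia, the resident macrophages of the brain, sorted by flow cytometry from whole brains of male Wistar rats. The sort gate kept viable cells with high CD11b and intermediate CD45 after a cold mechanical dissociation. Rats had received 14 Gy of X-rays or a sham irradiation. An intraperitoneal injection followed 6 weeks later, of phosphate-buffered saline (PBS, the vehicle) or of lipopolysaccharide (LPS, a bacterial cell wall component that activates innate immune cells). The 4 groups held 4 samples each, 16 libraries in all. The labels list separate samples and do not name the animals, so the p-values measure the spread between these samples. Total counts ranged from 16.8e6 to 22.5e6 in sham rats given PBS and from 16.6e6 to 19.8e6 in sham rats given LPS. In irradiated rats they ranged from 14.3e6 to 25e6 with PBS and from 19e6 to 62.7e6 with LPS. Counts of replicate libraries correlated with r between 0.939 and 0.971, and every one of the 24 replicate pairs differed by more than sampling noise (chi-square per degree of freedom 20.6 to 84.5). After filtering, 13608 genes were tested. Levels are given as CPM, scaled with TMM factors, with the SD over 4 libraries, and changes as log2 fold changes ± SE with n = 4 per group. Genes are said to have risen or fallen where the edgeR adjusted p was under 0.05. The largest changes are those among genes with a mean log2 CPM of at least 3, and in pairwise comparisons with groups that did not overlap.

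In sham-irradiated rats LPS raised genes of innate immune signalling in microglia. Bcl3, an atypical NF-kB inhibitor protein, rose by 5.92 ± 0.28 on the log2 scale (60.5-fold), from 1.13 ± 0.538 to 69.4 ± 15.3 CPM. Socs3, a feedback inhibitor of cytokine signalling, rose by 5.12 ± 0.22 (34.8-fold), and Cd14, a co-receptor for LPS, rose by 4.44 ± 0.54. The syndecan gene Sdc4 (4.65 ± 0.41), the immediate early gene Egr1 (4.47 ± 0.32) and Gm6377 (4.42 ± 0.42) were also among the largest increases. Il1b rose 11.2-fold, from 22.9 ± 1.77 to 257 ± 100 CPM, Tnf rose 10.5-fold and Ccl2 rose 7.55-fold. The granzyme genes Gzmbl2 (6.75 ± 0.90) and Gzma (4.78 ± 0.70), typical of cytotoxic lymphocytes, rose as well. Gzmbl2 belongs to a family of near-identical genes whose reads can be split between copies. The largest decreases were in Ighm, the immunoglobulin mu heavy chain gene (-3.20 ± 0.20), Rgs18 (-3.05 ± 0.35), Ypel2 (-2.96 ± 0.28) and the channel gene Calhm2 (-2.74 ± 0.21). Next came the lysophosphatidic acid receptor gene Lpar5 (-2.46 ± 0.29), Cytip (-2.42 ± 0.27), Engase (-2.22 ± 0.21) and Fam83d (-2.21 ± 0.24).

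Among NF-kB target cytokines and regulators, 33 of 47 measured members rose and 0 fell (35 and 0 adjusted over the list alone; camera adjusted p = 4.47e-31). They included Pim1 at 6.05 ± 0.31, Nfkbiz at 2.86 ± 0.18 and the adhesion molecule gene Icam1 at 1.86 ± 0.12. Of 29 negative regulators of innate signalling, 19 rose and 1 fell (19 and 1 adjusted over the list alone), including the phosphatase gene Ptpn1 (2.33 ± 0.08) and Il4r (2.59 ± 0.18). Chemokines rose in 14 of 20 cases with 0 falling (14 and 1 adjusted over the list alone), among them Cxcl10 (3.82 ± 0.29), Cxcl2 (4.60 ± 0.47) and Cxcl11 (5.00 ± 0.52). Of 22 interferon-gamma-inducible genes 16 rose (17 adjusted over the list alone), among them Irf1 (2.51 ± 0.18) and Gch1 (3.35 ± 0.23). Immediate early and dissociation-linked genes rose in 16 of 24 cases (19 adjusted over the list alone), with Btg2 at 3.08 ± 0.12 and Zfp36 at 3.06 ± 0.13. Glucocorticoid-responsive genes rose in 16 of 21 cases (17 adjusted over the list alone), with Fkbp5 at 4.40 ± 0.34. These 6 lists are the ones of this comparison whose camera calls held with an estimated correlation. Type I interferon response genes rose in 30 of 57 cases and fell in 2 (32 and 2 adjusted over the list alone), with Irgm at 2.04 ± 0.20 and Eif2ak2 at 1.57 ± 0.18. Libraries differed: the list mean (log2 CPM) was 4.261 in sham LPS 1, within the 3.767 to 4.291 of sham PBS libraries. In sham LPS 2, 3 and 4 it was 5.037, 5.75 and 4.984. The call (camera adjusted p = 4e-08) was lost in camera with the correlation estimated (adjusted p = 0.615 with an estimated correlation).

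Homeostatic microglial genes moved less under LPS in sham rats. Of 27 members 13 fell and 2 rose (14 and 3 adjusted over the list alone), the list median was -0.27 and the camera call was lost with an estimated correlation (adjusted p = 0.615 with an estimated correlation). P2ry12, a purinergic receptor gene, fell by 0.80 ± 0.18 on the log2 scale and Gpr34 fell by 1.31 ± 0.14. The fractalkine receptor gene Cx3cr1 fell by 0.37 ± 0.10 and Sall1, a transcription factor gene of microglial identity, fell by 0.40 ± 0.10. Tmem119 (0.19 ± 0.19, edgeR adjusted p = 0.494), Apoe (-0.12 ± 0.09, edgeR adjusted p = 0.341) and Clec7a (0.09 ± 0.24, edgeR adjusted p = 0.826) did not pass the test. T and NK cell markers rose in 10 of 28 cases and fell in 2 (11 and 2 adjusted over the list alone), a camera call lost in several ways: adjusted p = 0.752 with an estimated correlation, fry adjusted p = 0.0537, and camera adjusted p = 0.0952 without members shared with another list. With both irradiated libraries numbered 1 left out its camera adjusted p was 0.0517. Neutrophil genes rose in 4 of 17 cases and fell in 1, with a list median of 1.24. Their camera call was lost without members shared with another list (camera adjusted p = 0.238). In the edgeR quasi-likelihood test 4031 of 13608 genes changed, 2063 higher and 1968 lower (1927 and 2206 with library totals alone), and 751 of the higher and 574 of the lower genes changed at least 2-fold.

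The second comparison asked what irradiation alone had left in microglia 6 weeks later, in rats given PBS. Clec7a, which encodes the receptor dectin-1, rose 18.4-fold (4.20 ± 0.27), from 26.6 ± 2.65 to 489 ± 130 CPM. Gpnmb, a glycoprotein gene of lysosome-rich macrophages, rose 17-fold (4.09 ± 0.29), and Lgals3, which encodes galectin-3, rose 19.8-fold (4.31 ± 0.31). The calcium-activated potassium channel gene Kcnn4 (4.51 ± 0.24), the urokinase receptor gene Plaur (4.38 ± 0.34), Gzmbl2 (4.21 ± 0.89), the inhibitory receptor gene Lilrb4 (4.21 ± 0.34) and Gm6377 (3.98 ± 0.42) completed the largest increases. Of 27 genes of primed and disease-associated microglia 15 rose and 4 fell (17 and 5 adjusted over the list alone; camera adjusted p = 1.15e-17). Among them were Cd68 at 2.14 ± 0.12, Lyz2 at 2.36 ± 0.16 and the integrin gene Itgax at 3.71 ± 0.24. Il1b rose 2.43-fold (1.28 ± 0.27), whereas Tnf (0.04 ± 0.32, edgeR adjusted p = 0.95) and Ccl2 (0.79 ± 0.42, edgeR adjusted p = 0.217) did not pass.

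Homeostatic microglial genes fell together after irradiation: 24 of 27 fell and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 2.32e-30). The list median was -0.91. Tmem119 fell by 1.35 ± 0.19 on the log2 scale, from 5020 ± 989 to 1970 ± 467 CPM. P2ry12 fell by 1.15 ± 0.18, Sall1 fell by 1.08 ± 0.10 and Cx3cr1 fell by 0.90 ± 0.10. P2ry13 fell by 1.38 ± 0.11, the cystatin gene Cst3 fell by 1.09 ± 0.10 and the receptor gene Csf1r, needed for microglial survival, fell by 0.80 ± 0.07. Apoe fell by 0.31 ± 0.09, a call that was lost with library totals alone (edgeR adjusted p = 0.169) and without the sham PBS library 4 (0.0509) or the irradiated PBS library 2 (0.0557). The largest decreases were in the cadherin gene Cdh23 (-2.27 ± 0.14), the junction gene Jam2 (-2.24 ± 0.23), the endothelial matrix gene Mmrn2 (-2.16 ± 0.34) and Trim55 (-2.06 ± 0.16). They were followed by the potassium channel gene Kcnj15 (-2.03 ± 0.24), Mmp28 (-2.01 ± 0.21), Rcn3 (-1.88 ± 0.20) and Pls3 (-1.82 ± 0.30).

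Genes of border-associated macrophages, monocytes and T and NK cells were higher in the same libraries. Border-associated macrophage genes rose in 15 of 17 cases with 0 falling (15 and 1 adjusted over the list alone), with Folr2 at 2.40 ± 0.16, Clec10a at 2.79 ± 0.23 and Pf4 at 1.67 ± 0.13. Monocyte genes rose in 16 of 21 cases (17 adjusted over the list alone), with the integrin genes Itga4 at 2.27 ± 0.22 and Itgal at 1.60 ± 0.19. T and NK cell genes rose in 22 of 28 cases (24 adjusted over the list alone), with Klrk1 at 3.32 ± 0.48 and the T cell kinase gene Lck at 1.98 ± 0.31. That call was lost when camera estimated the correlation (adjusted p = 0.0725 with an estimated correlation). Neutrophil genes rose in 4 of 17 cases and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.454 with an estimated correlation), and B cell genes rose in 1 of 9 and fell in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.29). MHC class II antigen presentation genes rose in 8 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone), with the invariant chain gene Cd74 at 1.82 ± 0.15 and RT1-Da at 1.88 ± 0.16. Of 15 endothelial and mural cell genes 6 fell and 2 rose (6 and 2 adjusted over the list alone), with Tek at -1.31 ± 0.15 and Pecam1 at -1.07 ± 0.15. For that list the median was -0.39 and the test direction down while the mean was 0.23, and the call was lost with an estimated correlation (adjusted p = 0.148 with an estimated correlation).

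Cdkn1a, which encodes the cell cycle inhibitor p21, rose 11.8-fold after irradiation (3.57 ± 0.27), from 3.79 ± 0.965 to 44.6 ± 16 CPM. Senescence and secretory factor genes rose in 13 of 26 cases and fell in 1 (17 and 2 adjusted over the list alone), with the urokinase gene Plau at 3.39 ± 0.25 and the growth factor gene Hgf at 3.70 ± 0.47. Of 36 p53 targets and DNA damage response genes 10 rose and 2 fell (12 and 3 adjusted over the list alone), with Sulf2 at 2.03 ± 0.22, the death receptor gene Fas at 2.26 ± 0.28 and Ccng1 at 0.92 ± 0.12. Ribosomal protein genes rose in 65 of 67 cases with 0 falling (66 and 0 adjusted over the list alone), with Rplp0 at 1.21 ± 0.07 and Rps19 at 1.33 ± 0.09, in a family with many processed pseudogenes. Cell cycle genes rose in 24 of 56 cases and fell in 2 (29 and 2 adjusted over the list alone), with Ccnb2 at 1.74 ± 0.26 and Ttk at -1.15 ± 0.16. The call was lost in the same way (adjusted p = 0.051 with an estimated correlation). Cholesterol synthesis and uptake genes fell in 12 of 22 cases and none rose (13 and 0 adjusted over the list alone), with Msmo1 at -1.04 ± 0.10 and Hmgcs1 at -0.95 ± 0.12. This call too was lost (adjusted p = 0.051 with an estimated correlation). Type I interferon response genes rose in 29 of 57 cases (34 adjusted over the list alone), with Lgals3bp at 2.37 ± 0.14 and Oas1a at 2.97 ± 0.44, again without a call that held (adjusted p = 0.211 with an estimated correlation).

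In the edgeR test 2914 of 13608 genes changed with irradiation in rats given PBS, 1566 higher and 1348 lower, and of the changes of at least 2-fold 927 were higher and 216 lower. With library totals alone in place of TMM factors the median of all genes shifted by 0.156, and 2331 genes were higher and 725 lower (76.3% higher against 53.7%). Camera calls that held with an estimated correlation were those of the homeostatic, primed, border-associated macrophage, monocyte, MHC class II, ribosomal, senescence and p53 lists. Mitochondrial genes took 1.035% to 1.308% of the counts in sham libraries and 1.396% to 2.331% in irradiated ones, and the 10 most abundant genes took 17.23% to 17.62% with sham irradiation and PBS and 14.3% to 14.71% with irradiation and PBS. Both irradiated libraries numbered 1 carried more neural transcripts than the mean of the other 3 libraries of their groups, by at least 1.53 on the log2 scale for the oligodendrocyte, astrocyte and neuron lists. They also exceeded that mean in red cell genes (1.08 with PBS, 2.34 with LPS) and neutrophil genes (1.41 and 2.53). Neural transcripts were not limited to them: sham LPS 2 had list means of 4.085 for astrocytes and 4.142 for oligodendrocytes, against 4.088 and 4.741 in irradiated PBS 1. Neuron means were 0.755 and 0.924 in sham LPS 1 and 2, and -0.159 and -0.54 in sham LPS 3 and 4. With both irradiated libraries numbered 1 left out, 2341 genes changed, 1362 higher and 979 lower, and the homeostatic median was -0.83.

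**Figure D1:**
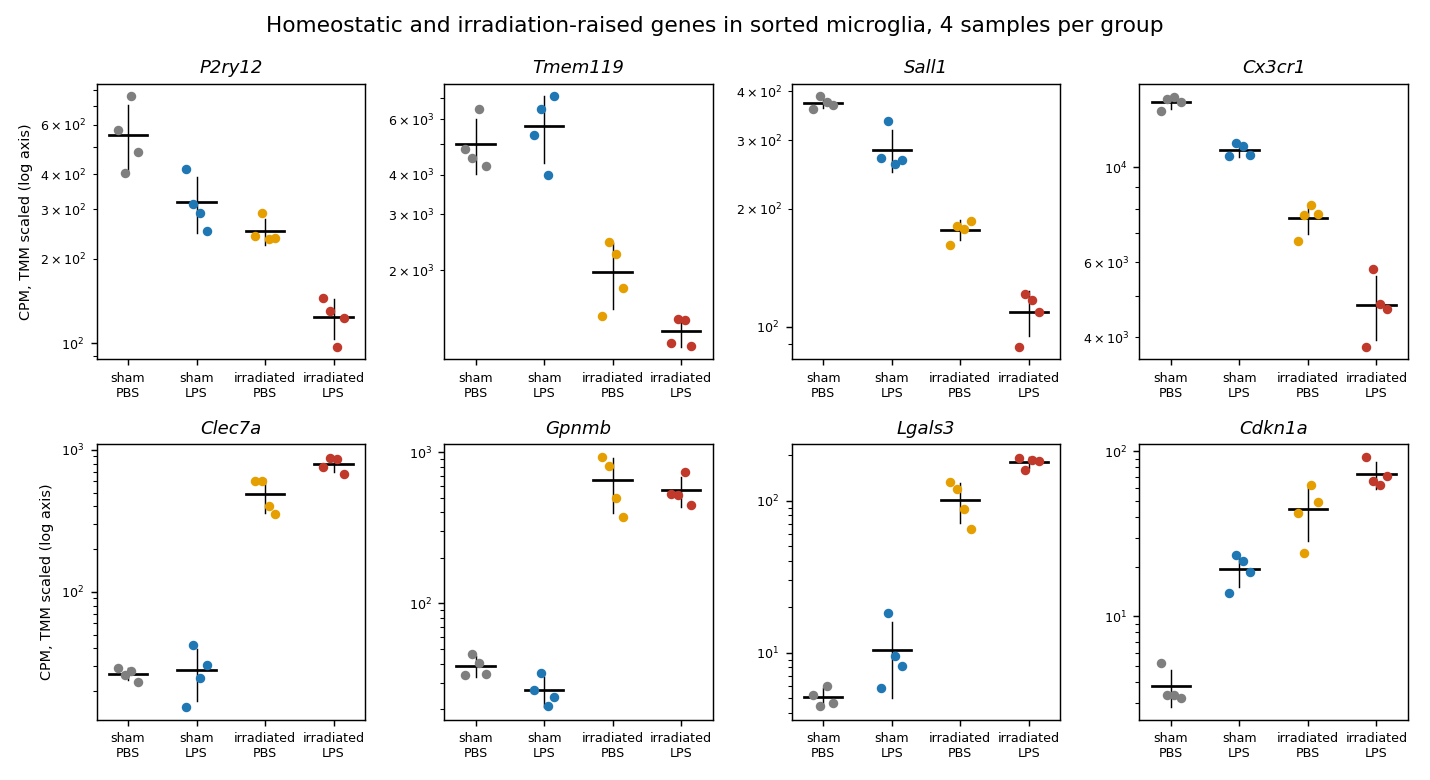
CPM of 8 genes on a log axis in the 4 groups, with a point per library, the mean as a horizontal line and the SD as a vertical line (n = 4). Mean Clec7a was 26.6 and 28.2 CPM in the sham groups and 489 and 793 CPM in the irradiated groups, while mean Sall1 stepped from 374 CPM in sham rats given PBS to 109 CPM in irradiated rats given LPS.

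LPS was also given to irradiated rats, to ask how a later immune challenge was met. Socs3 rose 44.3-fold (5.47 ± 0.23), Sdc4 rose 38.6-fold (5.27 ± 0.41) and the interferon-inducible chemokine gene Cxcl10 rose 27.4-fold (4.78 ± 0.30). Il1b rose 20.2-fold (4.34 ± 0.30), from 55.5 ± 7.06 to 1120 ± 458 CPM. Ccl7 (4.45 ± 0.44), Gzma (4.38 ± 0.60), Gzmbl2 (5.27 ± 0.74) and Bcl3 (4.31 ± 0.25) made up the rest of the largest increases, and Ccl2 rose 17.5-fold and Tnf 7.13-fold. The largest decreases were in Fam83d (-3.54 ± 0.26), Engase (-3.36 ± 0.22), the potassium channel gene Kcna2 (-3.16 ± 0.47), and the neuronal adhesion gene Icam5 (-2.97 ± 0.42). Calhm2 (-2.82 ± 0.20), Eva1a (-2.70 ± 0.15), the histamine receptor gene Hrh3 (-2.53 ± 0.35) and Fbxl20 (-2.48 ± 0.34) also fell.

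Of 47 NF-kB target cytokines and regulators 40 rose and 0 fell in irradiated rats (43 and 0 adjusted over the list alone; camera adjusted p = 2.54e-42). Sod2, the mitochondrial superoxide dismutase gene, rose by 3.81 ± 0.18 and Cflar by 1.59 ± 0.10. Interferon-gamma-inducible genes rose in 17 of 22 cases (17 adjusted over the list alone), with Cd274, which encodes the checkpoint ligand PD-L1, at 3.11 ± 0.21 and Gbp5 at 3.02 ± 0.21. Chemokines rose in 15 of 20 cases and fell in 1 (15 and 1 adjusted over the list alone), with Cxcl2 at 4.84 ± 0.41 and Cxcl11 at 5.79 ± 0.46. Inflammasome and pyroptosis genes rose in 10 of 18 cases and fell in 3 (10 and 3 adjusted over the list alone), with the caspase gene Casp4 at 1.12 ± 0.09 and the cytokine gene Il18 at 0.88 ± 0.10 (camera adjusted p = 0.0577 without members shared with another list). Negative regulators of innate signalling rose in 21 of 29 cases (22 adjusted over the list alone), glucocorticoid-responsive genes in 14 of 21 (15 adjusted over the list alone) and immediate early genes in 17 of 24 (18 adjusted over the list alone). Camera calls of these 7 lists held with an estimated correlation. Type I interferon response genes rose in 41 of 57 cases and fell in 1 (45 and 2 adjusted over the list alone), with Parp9 at 1.43 ± 0.09 and Stat2 at 1.37 ± 0.11. Their camera call was lost (adjusted p = 0.228 with an estimated correlation).

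Homeostatic genes fell in 19 of 27 cases and rose in 1 when irradiated rats received LPS (19 and 2 adjusted over the list alone), with a median of -0.62 and a camera call that did not hold (adjusted p = 0.179 with an estimated correlation). Gpr34 fell by 1.74 ± 0.14, P2ry12 fell by 1.02 ± 0.18, Sall1 fell by 0.69 ± 0.10 and Cx3cr1 fell by 0.68 ± 0.10, whereas Apoe (-0.18 ± 0.09, edgeR adjusted p = 0.126) did not pass except with library totals alone (0.00668). Tmem119 fell by 0.63 ± 0.19, Clec7a rose by 0.70 ± 0.23 and Cdkn1a rose by 0.71 ± 0.23. Each of these calls passed 0.05 by a small margin that some alternatives crossed, with folds of -0.50 to -0.58 for Tmem119, 0.57 to 0.72 for Clec7a and 0.50 to 0.72 for Cdkn1a where the call was lost. Without 1 library the edgeR adjusted p of Tmem119 was 0.0642 (irradiated PBS 2), 0.055 (irradiated PBS 3), 0.0527 (irradiated LPS 1) or 0.0558 (irradiated LPS 4). For Clec7a the edgeR adjusted p was 0.0973 or 0.1 without irradiated PBS 3 or 4, 0.0537, 0.0786 or 0.0782 without irradiated LPS 1, 2 or 3, and 0.0723 with library totals alone. For Cdkn1a the edgeR adjusted p was 0.0669 or 0.0746 without irradiated PBS 1 or 2, 0.0915 or 0.0525 without irradiated LPS 1 or 4, 0.145 without both irradiated libraries numbered 1, and 0.0593 with library totals alone. Neutrophil genes rose in 15 of 17 cases (15 and 1 lower adjusted over the list alone), with the receptor genes Cxcr2 at 4.92 ± 0.39 and Trem1 at 3.07 ± 0.33. Camera lost the call when it estimated the correlation (adjusted p = 0.338 with an estimated correlation). Irradiated LPS library 1 exceeded the mean of the other libraries of its group by 2.53 on the log2 scale in that list, and with both irradiated libraries numbered 1 left out 9 neutrophil genes rose and 1 fell. In the edgeR test 4277 of 13608 genes changed, 2309 higher and 1968 lower, and with library totals alone the median of all genes shifted by -0.118, with 1784 genes higher and 2768 lower (39.2% higher against 54%).

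Irradiated and sham rats that had both received LPS differed in many of the genes that separated the PBS groups. Clec7a was 28.1-fold higher (4.81 ± 0.28), Gpnmb 21-fold higher (4.39 ± 0.29), Lilrb4 20.7-fold higher (4.37 ± 0.33) and Kcnn4 20.5-fold higher (4.36 ± 0.23) in irradiated rats. The mitochondrial sulfide oxidation gene Sqor (4.18 ± 0.19), Plau (4.16 ± 0.26) and Ly49si2 (4.21 ± 0.31), a member of the clustered Ly49 receptor family, were also among the largest increases. RT1-CE16, a class I histocompatibility gene with close paralogs, had the largest fold (5.14 ± 1.48). Its levels ranged from 35.8 to 897 CPM within the irradiated LPS group. Without sham LPS library 1, 2 or 4 the edgeR adjusted p of RT1-CE16 was 0.0549, 0.0565 or 0.0534, and 0.0564 with both irradiated libraries numbered 1 left out, at folds of 4.70 to 5.17. Cdh23 (-2.90 ± 0.15) and the basement membrane collagen gene Col4a2 (-2.59 ± 0.71) fell most, followed by Fam83d (-2.49 ± 0.25), Mmp28 (-2.46 ± 0.21) and the collagen gene Col4a1 (-2.38 ± 0.70). Icam5 (-2.36 ± 0.41), Kcnj15 (-2.30 ± 0.24) and the cilium gene Tmem231 (-2.29 ± 0.32) came next. The calls of Col4a2 and Col4a1 were lost with both irradiated libraries numbered 1 left out (-2.43 and -2.12, edgeR adjusted p = 0.0595 and 0.0719). The Col4a1 call was also lost without sham LPS 2 (edgeR adjusted p = 0.0521) or irradiated LPS 1, 2 or 4 (0.0595, 0.0543 and 0.0521), and with replicate numbers as a block (0.0538), at folds of -2.13 to -2.41.

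Homeostatic genes fell in 24 of 27 cases and none rose (25 and 0 adjusted over the list alone), with a median of -1.22. Tmem119 fell by 2.16 ± 0.19, P2ry12 fell by 1.37 ± 0.18, Sall1 fell by 1.38 ± 0.10, Cx3cr1 fell by 1.21 ± 0.10 and Apoe fell by 0.37 ± 0.09. Primed and disease-associated genes rose in 16 of 27 cases and fell in 5 (16 and 5 adjusted over the list alone), with the oxidase gene Cybb at 3.37 ± 0.21 and Cd68 at 2.33 ± 0.12. MHC class II genes rose in 12 of 15 cases and fell in 3 (12 and 3 adjusted over the list alone), with RT1-Db1 at 2.84 ± 0.23 and Cd74 at 2.26 ± 0.16. Border-associated macrophage genes rose in 15 of 17 cases and fell in 1 (16 and 1 adjusted over the list alone), monocyte genes rose in 17 of 21 (18 adjusted over the list alone), and ribosomal protein genes rose in 64 of 67 (65 adjusted over the list alone). Senescence and secretory factor genes rose in 12 of 26 cases and fell in 1 (13 and 1 adjusted over the list alone), with Plaur at 3.86 ± 0.32. TGF-beta signalling genes fell in 12 of 25 cases and rose in 1 (13 and 2 adjusted over the list alone), with the receptor gene Tgfbr1 at -1.26 ± 0.10, and 7 fell with both irradiated libraries numbered 1 left out (camera adjusted p = 0.0869 without members shared with another list). Camera calls of these 8 lists held with an estimated correlation. Il1b was 4.38-fold and Ccl2 3.99-fold higher in irradiated than in sham rats given LPS, Cdkn1a was 3.75-fold higher, and Tnf (-0.51 ± 0.31, edgeR adjusted p = 0.265) did not pass.

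Type I interferon response genes were higher in irradiated rats given LPS in 48 of 57 cases and lower in none (51 and 0 adjusted over the list alone), with Gbp2 at 1.77 ± 0.18 and Ddx58, which encodes the RNA sensor RIG-I, at 1.27 ± 0.16. That camera call did not hold (adjusted p = 0.0963 with an estimated correlation). Chemokines were higher in 16 of 20 cases and lower in none (16 and 0 adjusted over the list alone), with Cxcl16 at 2.40 ± 0.17 and Cxcl10 at 2.03 ± 0.26, and lost their call likewise (adjusted p = 0.0532 with an estimated correlation). NF-kB targets were higher in 24 of 47 cases and lower in 7 (26 and 7 adjusted over the list alone), with Traf1 at 2.67 ± 0.26 and Birc3 at 1.92 ± 0.22 (adjusted p = 0.136 with an estimated correlation). T and NK cell genes were higher in 21 of 28 cases (24 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). Neutrophil genes were higher in 14 of 17 cases (15 and 1 lower adjusted over the list alone; adjusted p = 0.288 with an estimated correlation), and in 8 with both irradiated libraries numbered 1 left out. In the edgeR test 3771 of 13608 genes differed, 2055 higher and 1716 lower in irradiated rats (2442 and 1389 with library totals alone).

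**Figure D2:**
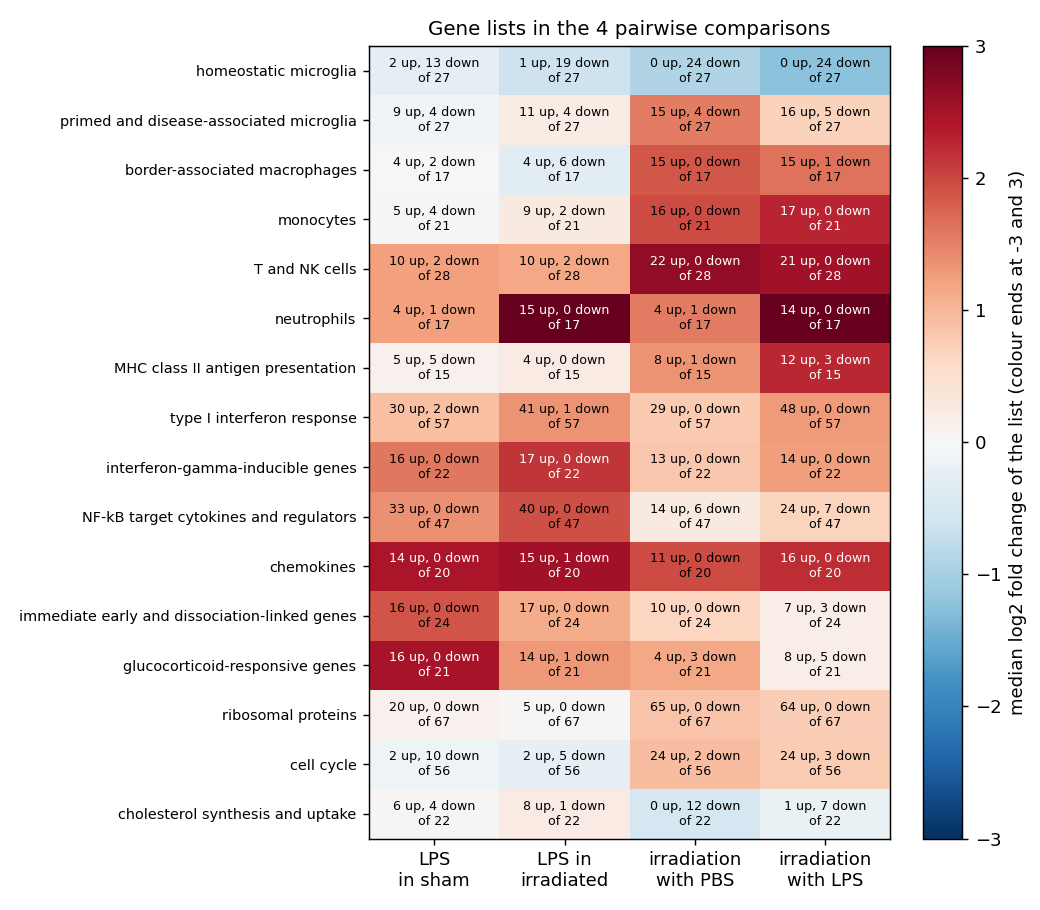
Median log2 fold change (colour) of 16 gene lists in the 4 pairwise comparisons, with the numbers of members that rose and fell (edgeR adjusted p under 0.05) in each cell. Homeostatic genes fell in 24 of 27 cases in both irradiation comparisons, and NF-kB targets rose in 33 and 40 of 47 cases in the LPS comparisons.

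The LPS responses of sham and irradiated rats, which share no library, correlated across 13608 genes with Pearson's r = 0.692 and Spearman's rho = 0.644, where genes are not independent replicates. Among genes with a mean log2 CPM of at least 3 (8256 genes), r was 0.812. In both comparisons 1494 genes rose and 1228 fell, against 350 and 285 for independent lists of these lengths, and 24 genes changed in opposite directions. Irradiation effects with PBS and with LPS correlated with r = 0.706, with 1192 genes higher and 903 lower in both, against 236 and 170 for independent lists, and 26 opposite.

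**Figure D3:**
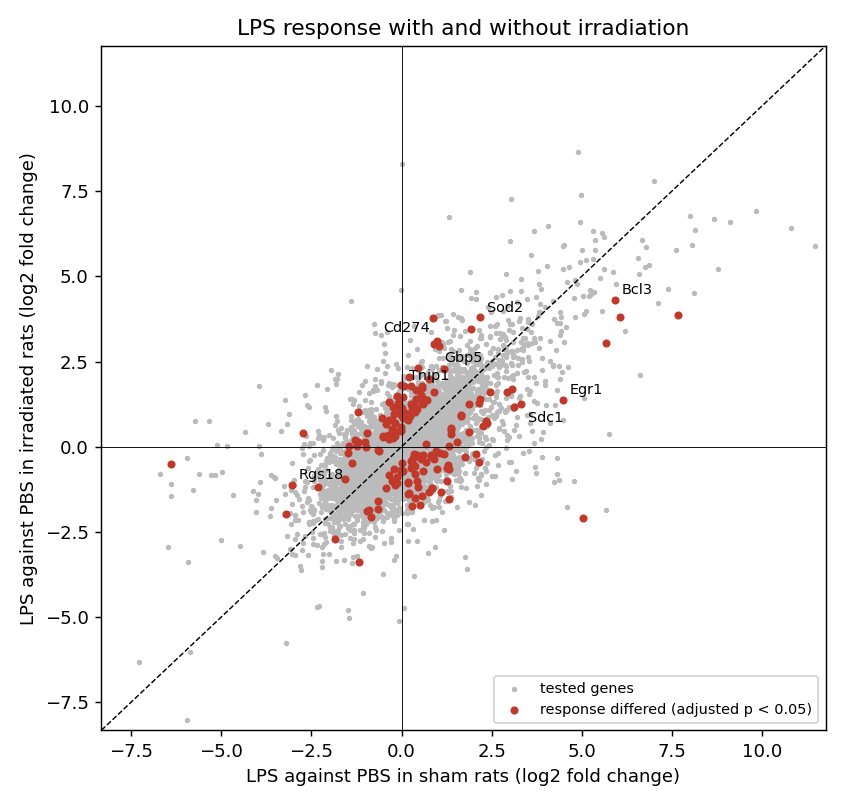
Log2 fold changes after LPS in sham rats (x axis) and irradiated rats (y axis), with a point per tested gene and the 171 genes whose response differed in red; the dashed line marks equal responses. Cd274 lay at 0.99 in sham and 3.11 in irradiated rats, and Egr1 at 4.47 and 1.38.

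The interaction contrast tested directly whether the LPS response differed with irradiation. Cd274 rose by 2.13 ± 0.29 more on the log2 scale in irradiated rats than in sham rats, from 5.86 ± 0.566 to 50.8 ± 12 CPM against 7.5 ± 1.46 to 14.9 ± 3.67 CPM (edgeR adjusted p = 0.00102). The interferon-inducible GTPase gene Gbp5 (2.12 ± 0.28), the interleukin-1 receptor accessory gene Il1rap (1.84 ± 0.29) and Tnip1, which encodes an A20-binding inhibitor of NF-kB (1.81 ± 0.24), also had more positive responses after irradiation. So did the iron-sensing ubiquitin ligase gene Fbxl5 (1.69 ± 0.18), the protease inhibitor gene Serpinb1a (1.65 ± 0.25), the phosphodiesterase gene Pde4b (1.62 ± 0.23), Sod2 (1.62 ± 0.23) and the metalloreductase gene Steap4 (1.52 ± 0.17). Fbxl5 stayed between 65.4 and 70.1 CPM in the other groups and reached 223 ± 41.1 CPM in irradiated rats given LPS. Egr1 differed in the other direction (-3.09 ± 0.40): it rose from 4.56 ± 1.27 to 102 ± 26 CPM in sham rats and from 12 ± 3.35 to 31.1 ± 11.3 CPM in irradiated rats. Sdc1 (-2.05 ± 0.34), Rnf187 (-2.02 ± 0.27), the mitochondrial reductase gene Mtarc1 (-2.01 ± 0.40), the polyamine synthesis gene Odc1 (-1.96 ± 0.34), Snx20 (-1.90 ± 0.31), Crtapl1 (-1.88 ± 0.36) and the metallopeptidase gene Amz1 (-1.83 ± 0.23) had more negative responses. Sdc1 went from 2.98 ± 0.425 to 29.6 ± 12.6 CPM in sham rats and from 24.5 ± 5.98 to 58.3 ± 8.24 CPM in irradiated rats. Given LPS, mean Sdc1 and Odc1 were thus higher in irradiated than in sham rats, and the others listed here were lower.

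Smaller margins applied to Rgs18 (1.93 ± 0.45, edgeR adjusted p = 0.047), Pithd1 (-2.43 ± 0.55, edgeR adjusted p = 0.0379), Rcn2 (-2.07 ± 0.43, edgeR adjusted p = 0.0285) and Cdkn1a (-1.66 ± 0.35, edgeR adjusted p = 0.0267). Leaving out any of 13 single libraries ended the call of Rgs18, any of 10 that of Pithd1, any of 8 that of Rcn2 and any of 7 that of Cdkn1a. The highest edgeR adjusted p without 1 library was 0.0974 for Rgs18 (irradiated PBS 4), 0.0851 for Pithd1 (irradiated PBS 3), 0.0675 for Rcn2 (irradiated LPS 4) and 0.0713 for Cdkn1a (sham PBS 3). With both irradiated libraries numbered 1 left out the edgeR adjusted p was 0.125 for Rgs18, 0.0729 for Pithd1 and 0.0701 for Rcn2, and with replicate numbers as a block it was 0.0614 for Rgs18. Where these calls were lost the differences were 1.67 to 2.06 for Rgs18, -2.05 to -2.55 for Pithd1, -1.90 to -2.14 for Rcn2 and -1.55 to -1.65 for Cdkn1a. P2ry12, Tmem119, Cx3cr1, Sall1, Apoe, Clec7a, Il1b, Tnf and Ccl2 did not pass, with differences of -0.22 ± 0.26, -0.81 ± 0.26, -0.31 ± 0.14, -0.30 ± 0.14, -0.06 ± 0.12, 0.61 ± 0.34, 0.85 ± 0.38, -0.55 ± 0.45 and 1.21 ± 0.57, and edgeR adjusted p from 0.186 to 0.913. Tmem119 passed in DESeq2 (-0.82, DESeq2 adjusted p = 0.0374).

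Of the 171 genes that passed, 83 were more positive and 88 more negative after irradiation (86 and 135 with replicate numbers as a block, 83 and 120 with the mean of the neural lists as a covariate), and 1626 genes had an unadjusted p under 0.05. Irradiation with PBS, a comparison that shares its libraries with the interaction, had also changed 91 of the 171. Among NF-kB targets 7 of 47 had a more positive and 2 a more negative response (11 and 4 adjusted over the list alone) (camera adjusted p = 0.00145; adjusted p = 0.484 with an estimated correlation). Pim1 differed by -2.24 ± 0.40 and Casp4 by 0.69 ± 0.13. The Casp4 call was lost with both irradiated libraries numbered 1 left out (0.64, edgeR adjusted p = 0.0537). Type I interferon response genes had a median difference of 0.38, and 3 of 57 passed (8 adjusted over the list alone; camera adjusted p = 2.19e-07; adjusted p = 0.652 with an estimated correlation). These were Gbp5, Stat2 (0.67 ± 0.16) and Ddx58 (0.93 ± 0.22). Both calls were fragile: leaving out any of 12 single libraries ended that of Stat2 and any of 13 that of Ddx58, with the highest edgeR adjusted p of 0.106 and 0.0976 without sham PBS 1. With replicate numbers as a block the edgeR adjusted p was 0.0539 and 0.0699, with library totals alone 0.062 and 0.0507, and with both irradiated libraries numbered 1 left out 0.11 and 0.146. Where these calls were lost the differences were 0.57 to 0.70 for Stat2 and 0.79 to 0.99 for Ddx58. Of 24 immediate early genes 2 had a smaller response, Egr1 and Btg2 (-1.39 ± 0.16), with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.1e-05; adjusted p = 0.265 with an estimated correlation). For homeostatic genes the median difference was -0.25, with 0 of 27 passing (4 lower adjusted over the list alone; camera adjusted p = 4.6e-05; adjusted p = 0.484 with an estimated correlation). Glycolysis and HIF-1 target genes included Hif1a (0.77 ± 0.12) and the glucose transporter gene Slc2a1 (1.15 ± 0.22) among 3 of 26 with a more positive response (5 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.634 with an estimated correlation). The remaining gene, Pfkl (0.49 ± 0.11, edgeR adjusted p = 0.0413), lost its call without any of 14 single libraries. Its call was also lost with library totals alone (0.40, edgeR adjusted p = 0.1). None of the 13 list calls of the interaction held with an estimated correlation, and only the immediate early and TGF-beta lists held in fry (fry adjusted p = 0.0369 for both). Among the 13 were the neutrophil list (more positive, 0 of 17 members passing) and the astrocyte list (more negative, 0 of 16 passing). Mean log2 CPM of the neutrophil list was 0.07 ± 0.68 and 1.59 ± 0.64 in sham rats given PBS and LPS. In irradiated rats it was 1.38 ± 0.84 and 4.48 ± 1.36. Whether neutrophils in the gate contributed to the genes with a different response was not tested.

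The interaction count depended on single libraries. It fell to 113 genes without sham PBS 1, 103 without sham PBS 3, 112 without irradiated PBS 3, 111 without irradiated PBS 4 and 109 without irradiated LPS 4, and to 98 with both irradiated libraries numbered 1 left out, of which 88 were among the 171. DESeq2 called 427 genes, and a test against a fold change of 1.5 left 23. With library totals alone 63 genes were more positive and 162 more negative (28% against 48.5%).

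**Figure D4:**
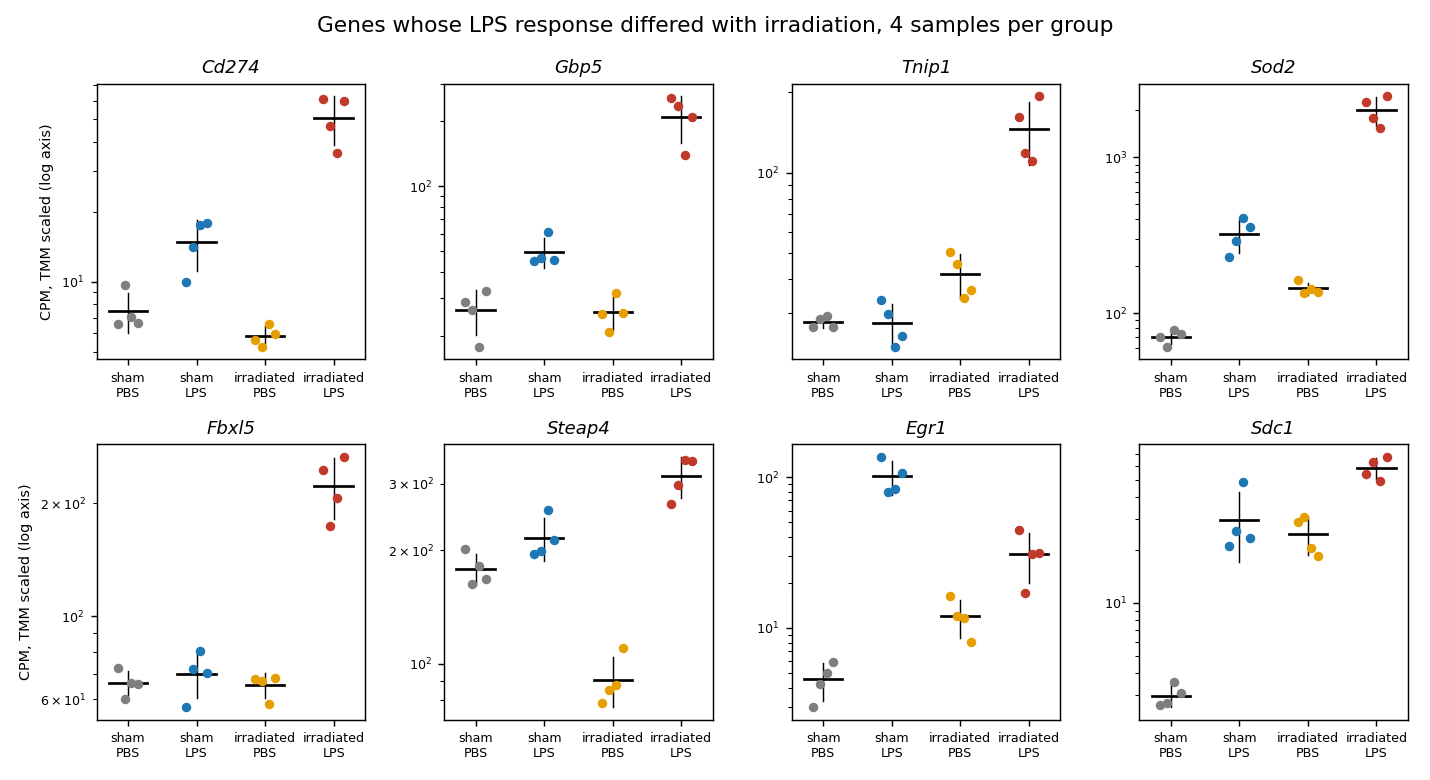
CPM of 8 genes whose LPS response differed with irradiation, on a log axis, with a point per library, the mean as a horizontal line and the SD as a vertical line (n = 4). Mean Sod2 was 70.7 and 322 CPM in sham rats without and with LPS, and 144 and 2020 CPM in irradiated rats.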

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

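The tests on Sall1, on scaling, on depth and on neural RNA carried through the sort were chosen after the results were seen. Predictions for the other tests were written down before. Some of these, leaving out or relabelling both irradiated libraries numbered 1, concern libraries that were picked out after the data were seen. A library was flagged where it lay far from the other 3 of its group (1 in 20 by chance), which found 28 cases among 448 groups of values, against 22 expected by chance. The value given is the gap to the nearest library as a share of the range of the group.

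Among list means, sham LPS 3 was lowest for homeostatic microglia (0.845), and sham LPS 1 was lowest for MHC class II (0.914) and ribosomal proteins (0.883). Irradiated LPS 4 was highest for inflammasome genes (0.847), irradiated LPS 1 lowest for cell cycle (0.882) and irradiated LPS 2 lowest for lipid efflux (0.89). Sham PBS 2 was lowest for oxidative phosphorylation (0.908), sham PBS 1 lowest for cholesterol synthesis (0.965) and sham PBS 3 highest for neurons (0.908). Among genes, low values were found for Cd14 (0.856, irradiated PBS 1), Gm6377 (0.834, sham PBS 3), Lpar5 (0.834, irradiated PBS 4), Apoe (0.857, irradiated LPS 4), Ccl2 (0.897, irradiated PBS 3) and Trim55 (0.846, irradiated LPS 1). Kcna2 (0.975, sham LPS 3), Fbxl20 (0.949, sham PBS 1), Fbxl5 (0.912, irradiated PBS 3) and Rcn2 (0.859, sham PBS 1) were low as well. High values were found for P2ry12 (0.887, irradiated PBS 2), Sall1 (0.856, sham LPS 2), Cdkn1a (0.912, sham PBS 1), Plau (0.853, sham LPS 1), Gbp5 (0.914, sham LPS 3), Serpinb1a (0.864, irradiated LPS 1) and Crtapl1 (0.859, irradiated LPS 3). RT1-CE16 was high in sham PBS 3 (0.939, 321 CPM) and low in irradiated LPS 2 (0.833, 35.8 CPM).

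Genes flagged for a different LPS response (irradiated minus sham, log2) were Cd274 (2.13), Gbp5 (2.12), Rgs18 (1.93), Il1rap (1.84), Tnip1 (1.81), Fbxl5 (1.69), Serpinb1a (1.65), Pde4b (1.62), Sod2 (1.62) and Steap4 (1.52). Negative differences were those of Egr1 (-3.09), Pithd1 (-2.43), Rcn2 (-2.07), Sdc1 (-2.05), Rnf187 (-2.02), Mtarc1 (-2.01), Odc1 (-1.96), Snx20 (-1.90), Crtapl1 (-1.88), Amz1 (-1.83) and Cdkn1a (-1.66).

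Microglial identity genes were lower and macrophage genes higher after irradiation in rats given PBS. Dilution by cells without Sall1 inside the gate would lower no microglial gene more than Sall1 itself (-1.08), and 1 of 27 members of the homeostatic list (3.7%), P2ry13 at -1.38 ± 0.11, lay below it by more than 2 SE. Members that fell less than Sall1 are allowed under dilution and without it, so dilution stays open for the list, next to a change within microglia. Single genes of large decrease, such as Cdh23 (-2.27 ± 0.14), fell further than dilution of a gene of microglia alone allows, but they were picked for their size and settle nothing for the list. The homeostatic list median of -0.91 was -0.76 with library totals alone, which shifted the median of all genes by 0.156, so the choice between these scalings did not account for the decrease, and it was -0.83 without both irradiated libraries numbered 1.

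Genes with a different LPS response could reflect depth, since irradiated LPS libraries were the deepest. After thinning to 14.3e6 counts 85.4% of the 171 genes were called again. Without both irradiated libraries numbered 1 the differences had a median ratio of 1.002 to their first value and 171 of 171 kept their sign, and 88 were called again. The genes were picked in data that included the libraries kept, so the kept signs and the ratio were largely given in advance. When labels were exchanged within the arms, 3 of 100 splits gave as many genes as the real one, itself included. The other splits gave a median of 0 genes. Exchanged labels put irradiated and sham libraries in the same group, so the irradiation difference widened the spread within groups. These splits therefore do not measure how often an interaction of this size arises by chance. The highest other count was 515, from a split that kept the LPS arm and mixed the PBS arm, so that the irradiation difference in the LPS arm entered the contrast.

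Neural transcripts were higher in both irradiated libraries numbered 1. The oligodendrocyte, astrocyte and neuron lists exceeded the mean of the other 3 libraries by at least 1.53 on the log2 scale. These are the lists that showed the pattern, so the value supports no explanation, and the source of the transcripts stays open. The same libraries exceeded that mean in red cell genes (1.08 with PBS and 2.34 with LPS) and neutrophil genes (1.41 and 2.53), and sham LPS 2 was also high in astrocyte (4.085) and oligodendrocyte (4.142) list means. A wrong label was not supported: both libraries correlated better with their own group than with any other, by at least 0.029. For the pairwise comparisons only 1 of 35 splits, the real one itself, gave as many genes. The highest other counts were 6 (LPS in sham), 0 (irradiation with PBS), 0 (LPS in irradiated) and 4 (irradiation with LPS). These other splits also mixed libraries of both conditions in a group, so the real difference widened the spread within groups. Such counts therefore do not measure how many genes would be called by chance.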

How the results depend on the processing

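Counts of changed genes in the pairwise comparisons stayed within 1.5 times their value under every alternative except the test against a fold change of 1.5, which by construction left 937 (LPS in sham), 831 (irradiation with PBS), 1142 (LPS in irradiated) and 1270 (irradiation with LPS). Leaving out 1 library, which also refilters the genes, gave 3316 to 4118, 2325 to 2971, 3568 to 4376 and 3220 to 3740 genes. The interaction count of 171 was less stable: DESeq2 gave 427, the test against a fold change of 1.5 gave 23, and leaving out sham PBS 1, sham PBS 3, irradiated PBS 3, irradiated PBS 4 or irradiated LPS 4 gave 113, 103, 112, 111 and 109 (103 to 191 over all libraries); the cause was not tested beyond the smaller number of samples. Alternatives added after the data were seen were leaving out both irradiated libraries numbered 1 (4011, 2341, 3653, 3227 and 98 genes), thinning to the smallest total (3994, 2868, 4187, 3695 and 157) and the mean of the neural lists as a covariate (4106, 2649, 4450, 3936 and 203). The similarity of the LPS responses (0.692) was 0.812 among genes with a mean log2 CPM of at least 3, and 0.637, 0.632 and 0.636 without sham PBS 1, 2 and 4, 0.634 and 0.63 without sham LPS 2 and 3, 0.633 without irradiated PBS 2, and 0.616 and 0.643 without irradiated LPS 1 and 4 (0.616 to 0.662 over all libraries); the cause was not tested. Replicate numbers as a block gave 4168, 3038, 4446, 3875 and 221 genes. Residuals of libraries with the same number correlated with a median of 0.09 (24 pairs, -0.089 to 0.405, 10 over 0.1), against -0.03 for 72 other pairs, and 3 libraries correlated best with their own number in all groups, a hint from the data and not from the design. Residuals cancel out within a group, so the value of the other pairs is tied to the first and is no separate comparison. The highest value, 0.405, was that of both irradiated libraries numbered 1. Of 98 called list results 29 held with an estimated correlation, 85 in fry, 92 with library totals alone, 97 with the block, 71 without members shared with another list and 91 without both irradiated libraries numbered 1. Of 458 results of named genes 410 were called, 13 of these lost the call without some library and 0 reversed. Except for the fixed panel these genes were named for a large fold or a small p in the same data, which favours calls that hold. Reversals occurred only in genes that were not called: Clec7a after LPS in sham rats (-0.17 without sham LPS 2, 0.29 without sham LPS 1), Tnf after irradiation with PBS (-0.04 with the block, -0.05 without sham PBS 2, -0.14 without irradiated PBS 3 or 4, 0.21 without irradiated PBS 1) and Apoe in the interaction (0.02 without irradiated PBS 3, -0.12 without irradiated PBS 2). Thinning to 14.3e6 counts moved the interaction count only from 171 to 157, and lower depths were not tested.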

Other observations

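Oxidative stress and NRF2 target genes rose after irradiation in rats given PBS: 16 of 30 members rose and 0 fell (19 and 3 adjusted over the list alone), with the oxidase gene Cybb at 2.90 ± 0.21, Osgin1 at 2.90 ± 0.24 and Mgst1 at 3.06 ± 0.36 (n = 4; camera adjusted p = 1.47e-06; adjusted p = 0.0692 with an estimated correlation). Oxidative phosphorylation genes rose in 26 of 66 cases (27 adjusted over the list alone; adjusted p = 0.381 with an estimated correlation), with Cox4i1 at 0.64 ± 0.09. Unfolded protein response genes fell in 10 of 23 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), with the chaperone gene Hspa5 at -0.49 ± 0.09 and the opposite change in Asns (2.41 ± 0.36). Complement genes rose in 7 of 20 cases and fell in 4 (8 and 4 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation), with C4b at 1.68 ± 0.34 and Cd59 at 2.52 ± 0.25.

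After LPS in irradiated rats proteasome genes rose in 19 of 31 cases (20 adjusted over the list alone; camera adjusted p = 0.000417; adjusted p = 0.592 with an estimated correlation), with Psma6 at 0.64 ± 0.09 and Psmc1 at 0.56 ± 0.09. In sham rats 8 of 31 rose (8 adjusted over the list alone; adjusted p = 0.752 with an estimated correlation), with Psmc1 at 0.56 ± 0.09. Purinergic receptor and ion channel genes were lower in 13 of 26 cases and higher in 6 in irradiated rats given LPS (13 and 8 adjusted over the list alone; adjusted p = 0.267 with an estimated correlation), with Entpd1 at -1.14 ± 0.10 and Kcnn4 at 4.36 ± 0.23. For this list the median was -0.41 and the mean 0.02.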
